A study of Caenorhabditis elegans with 9 samples.

How the data were processed

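The arrays were NimbleGen one-colour arrays labelled with Cy3, from 5 µg of total RNA each, of animals grown at 20 °C and infected for 24 h. The probe files held linear intensity values that the authors had deposited after RMA background correction and quantile normalization, per the file headers and the submitters' processing notes, which name RMA without a version. Each array held 136882 probes of 23187 targets, with median probe intensities of 434.67 to 434.79. Between 31.6% and 32.3% of genes lay under an intensity of 100 on each array. Parameters of the authors' background correction were not given in the sources used here.

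The gene value was the median polish of the log2 probe intensities of a target. For genes with several targets, 1 target per gene was used, the target with the highest mean over all 9 arrays. Target names came from the file's own identifiers, and 22582 of 23187 targets were matched to the supplied table of gene names, 605 keeping the name of the file, for 20018 genes. Among 2273 genes with several targets, targets of 4, 15 and 7 genes were called both ways in the kin-1, crh-1 and direct comparisons. No genome build was stated, so no positions are given, and the supplied table served only for names and for the order of neighbouring genes.

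The authors' deposited gene-level tables held linear intensities of 15404 and 15405 targets (12777 and 12778 genes), with 100.092 as the lowest value. The tables were identical where they overlapped, and they correlated across targets with the median polish used here at 0.999848 to 0.999866 on log2 scale. Of 15412 targets at 100 or more on all arrays here, 15383 were in the larger table, which left out tdpt-1. A floor of 100 was taken from that limit: a strain with all 3 arrays under it was treated as not measured, and the difference was then given as at least N-fold, from the mean of the brighter strain against the floor.

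The authors' deposited tables of differences held a fold and a p-value per target, per the file headers from a t-test at p 0.05 with a fold of 1.5. The header called the fold log2, but the fold values were linear ratios of 1.5 or more. A t-test on the log2 of the authors' deposited values gave all p-values and all geometric folds of the 568 and 376 targets of the kin-1 comparison, the 1149 and 1404 of the crh-1 comparison and the 1066 and 718 of the direct comparison within 1%. The genes of those tables were called the same way here in 97.3%, 98.6%, 98.5%, 98.7%, 98.8% and 97.4% of cases, and in the opposite way in 1, 0, 0, 1, 0 and 1 genes.

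Differences were tested with limma 3.58.1 (lmFit, contrasts and eBayes, 2-sided) in R 4.3.3 with the package data.table, version 1.17.8, in 1 fit of all 9 arrays with the genotype as the only factor. The p-values were adjusted by Benjamini-Hochberg over the 20018 genes of a comparison, and a gene was called at an adjusted p under 0.05 with no fold threshold. Values are means of 3 arrays on log2 scale, and a difference is given with limma's standard error. The smallest p of an exact permutation test of 3 against 3 arrays is 0.1, so no permutation p was used for single genes. For orientation, the arrays of the strains compared did not overlap in 40.9%, 49.9% and 43.1% of genes, where 10% would be reached by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

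Shifts of 33 gene lists were tested with limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg over 99 tests. The lists were fixed before the data were examined, by symbols and by symbol families, and 3 given members (hsp-16.11, hsp-16.49 and F44E5.5) were not on the arrays. Of the 99 tests 45 passed, and 33 of those also passed with a correlation estimated per list. Members were counted by the adjusted p over all genes, and by an adjusted p over the list alone. The histone, reference gene and tissue lists were short hand-made lists or symbol families and do not cover their groups. Some lists share members, so their shifts are not independent. The epidermal list shares nhr-25 with the moulting list, dpy-7 and bli-1 with the collagens and elt-3 with epidermal immune signalling. The gene nlp-29 is in both the antimicrobial nlp and the osmotic stress list.

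The named genes followed a rule fixed before the data were seen. It took kin-1, crh-1, nlp-29, nlp-31, cnc-2 and cnc-4 in every comparison, then the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap, then up to 3 called members with the largest difference of each list in order of camera p up to 30 per comparison, and last the 3 largest shared rises and falls. All members of the lists were tested, but only a part of the genes so named is printed.

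The overlap of calls against the shared wild-type arrays was set beside 100 simulations of unchanged groups against those arrays. The fit was tested on simulated data in which 200 of 20018 genes were changed, 50 per size: 54%, 78%, 98% and 98% of genes changed by 1.5, 2, 3 and 4-fold were recovered, with 12 false calls and 0 of the wrong sign. In the real comparisons 22.5%, 37.9% and 28.4% of genes were called, and the adjusted p depends on that share. The rates of recovery and false calls therefore do not describe the reported fit. In the principal components the arrays of a strain lay together. This would hold as well if the labels of whole strains were exchanged, so it does not check the genotypes. The labels give each strain replicates 1 to 3 but name no shared batch.

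The alternatives tried were the mean of log2 probe values, both of the authors' gene-level tables, an offset of 50, median centring and cyclic loess between arrays, leaving out the dimmest 25% of genes, testing every target, fitting only the strains compared, trend and robust eBayes, array weights, a replicate block, a 2-fold threshold, the t-test with the authors' thresholds, and leaving out each array. Leaving out the 5560 genes under 100 on every array, and camera after cyclic loess, were chosen after the data were seen. The files name no slide, so no slide block was fitted. No sample was left out.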

Results

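The data were gene expression values from 9 one-colour microarrays of whole Caenorhabditis elegans, 3 arrays each of wild-type animals, animals labelled kin-1(ok338) and animals labelled crh-1(tz2), each array from its own culture. The kin-1 gene encodes the catalytic subunit of protein kinase A, and crh-1 encodes the worm's CREB transcription factor. All animals had been infected for 24 h with the fungus Drechmeria coniospora, and no uninfected animals were measured, so every difference is a difference between infected strains. Values were measured for 20018 genes, and a gene was called when limma's adjusted p was under 0.05. All arrays had the same amount of RNA and were quantile normalized. Higher, lower, more and less therefore refer to shares of an array's signal, not to amounts per animal. A fall of many genes can thus raise the shares of others. The arrays of each strain lay close together, with correlations across genes of 0.994 to 0.996 within strains and 0.982 to 0.989 between strains, the genes not being independent replicates. The first principal component held 46.0% of the variance and the second 23.2%. With 3 arrays per strain, small changes were measured with limited precision.

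Against wild type, the kin-1-labelled animals had more transcript of neuropeptides, of genes that act in epidermal immune signalling, of glutathione S-transferases and of cytochrome P450 genes. They had less of the listed sperm, oocyte and egg shell genes and of genes used in moulting, while major sperm proteins did not pass the test. The antimicrobial nlp peptides and the caenacins did not pass as groups, and the fungus-induced proteins passed only with the preset correlation. Of the 20018 genes, 2170 were higher and 2341 were lower in the kin-1-labelled animals, and 186 and 82 of them by a fitted difference of at least 2-fold. Counting only changes that measured levels or a bound put at 2-fold or more left 130 and 48. The median size of a called difference was 0.47 on the log2 scale. Without wild-type replicate 1, 1480 genes were lower. In 278 of the 4511 called genes both strains lay under an intensity of 100, the floor below which levels were taken as not measured.

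The gene with the largest fall in the kin-1-labelled animals was tdpt-1, a tyrosyl-DNA phosphodiesterase gene, whose mean went from 11.88 (SD 0.07) to 5.72 (SD 0.09), at least 37.7-fold lower (adjusted p = 3.84e-09). The fatty acid desaturase gene fat-5 fell from 10.68 (SD 0.07) to 8.38 (SD 0.12), a log2 difference of -2.29 ± 0.09 (adjusted p = 2.09e-06). T27E7.1 fell from 14.27 to 11.62 (log2 difference -2.65 ± 0.09, adjusted p = 1.36e-06) and the C-type lectin gene clec-45 from 9.04 to 6.98 (-2.06 ± 0.15, adjusted p = 7.29e-05). The chemoreceptor gene srw-85 was at least 4.14-fold lower (means 8.69 and 5.30, adjusted p = 3.15e-05), and the insulin-like gene ins-8 at least 1.98-fold lower (7.63 and 5.08, adjusted p = 0.000115). The largest rises with both strains above the floor included grl-20, a ground-like gene of the hedgehog-related group, from 8.23 to 11.65 (3.41 ± 0.07, adjusted p = 9.19e-08). The lectin gene clec-9 was at least 11.8-fold higher (6.50 and 10.21, adjusted p = 7.70e-07), the lipase-related gene lips-6 at least 8.20-fold (5.61 and 9.68, adjusted p = 2.11e-05) and the collagen gene col-37 at least 5.43-fold (5.74 and 9.09, adjusted p = 1.04e-05). C54F6.15 was at least 4.79-fold higher (5.34 and 8.90, adjusted p = 0.000124) and irld-53 at least 3.22-fold (4.16 and 8.33, adjusted p = 2.63e-05).

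Genes for FMRFamide-like neuropeptides rose as a group in the kin-1-labelled animals. Of 31 members, 27 were higher and 0 lower over all genes (28 and 0 adjusted over the list alone; median log2 difference 0.47, camera adjusted p = 1.67e-14). The gene flp-18 rose from 11.15 to 12.36 (1.21 ± 0.09, adjusted p = 8.11e-05) and flp-12 from 10.40 to 11.23 (0.83 ± 0.08, adjusted p = 0.00034). The gene flp-25 was at least 1.03-fold higher (5.76 and 6.69, adjusted p = 0.0157), a call lost without wild-type replicate 1 (adjusted p = 0.0572), wild-type replicate 3 (0.0532) or kin-1 replicate 2 (0.0528). Of 19 neuronal genes, 7 were higher and 0 lower (11 and 0 over the list alone; median 0.25, adjusted p = 2.32e-05). Among them egl-21, whose carboxypeptidase processes neuropeptides, rose by 0.71 ± 0.10 (adjusted p = 0.00195) and ida-1, which acts in dense-core vesicles, by 0.46 ± 0.07 (adjusted p = 0.00292). The synaptotagmin gene snt-1 rose by 0.59 ± 0.13 (adjusted p = 0.0147), a call lost without wild-type replicate 2 (0.0531) or kin-1 replicate 1 (0.0509).

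Listed sperm, oocyte and germline genes fell in the kin-1-labelled animals. None of 30 major sperm proteins was called (median -0.06, adjusted p = 0.124). Of 50 sperm genes, 0 were higher and 30 lower (0 and 37 over the list alone; median -0.36, adjusted p = 4.37e-12). The sperm fusion gene fer-1 was at -0.65 ± 0.13 (adjusted p = 0.00963), spe-57 at -0.63 ± 0.11 (adjusted p = 0.00423) and spe-15 at -0.63 ± 0.11 (adjusted p = 0.0053). Of 25 oocyte and egg shell genes, 0 were higher and 19 lower (0 and 22 over the list alone; median -0.32, adjusted p = 1.04e-08). The maternal factor gene pie-1 differed by -0.51 ± 0.11 (adjusted p = 0.0135; call lost with a t-test after Benjamini-Hochberg, 0.0749), the chitin synthase gene chs-1 by -0.49 ± 0.08 (0.00423) and the yolk receptor gene rme-2 by -0.46 ± 0.07 (0.00352). Of 24 genes of germline proliferation and meiosis, 0 were higher and 6 lower (0 and 7 over the list alone; median -0.21, adjusted p = 0.000253). In that list mcm-7 differed by -0.33 ± 0.08 (adjusted p = 0.0144), a call lost without wild-type replicate 1 (0.0554) or 2 (0.0508). There gld-1 differed by -0.46 ± 0.12 (adjusted p = 0.0251), lost without wild-type replicates 1 (0.0789) or 2 (0.0671) or kin-1 replicates 1 (0.0687) or 2 (0.0744).

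Moulting genes fell and their regulator nhr-25 rose in the kin-1-labelled animals. Of 18 moulting genes, 1 was higher and 15 lower (1 and 16 over the list alone; median -0.52, adjusted p = 6.9e-08). The protease inhibitor gene mlt-11 fell from 12.27 to 11.42 (-0.85 ± 0.09, adjusted p = 0.000699) and qua-1 from 12.27 to 11.54 (-0.73 ± 0.10, adjusted p = 0.00173), while the nuclear receptor gene nhr-25 rose from 8.47 to 9.43 (0.96 ± 0.11, adjusted p = 0.00072). Of 176 cuticle collagens, 21 were higher and 64 lower (26 and 72 over the list alone; median -0.18, adjusted p = 0.00279).

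Epidermal immune signalling genes rose in the kin-1-labelled animals, with 10 of 23 higher and 0 lower (13 and 0 over the list alone; median 0.28, adjusted p = 1.39e-05). The TGF-beta receptor gene sma-6 rose by 0.73 ± 0.09 (adjusted p = 0.00109), the Smad gene sma-2 by 0.69 ± 0.09 (0.00146) and the STAT-like gene sta-2 by 0.62 ± 0.08 (0.00117). The antimicrobial nlp peptides showed no shift: 2 of 10 were higher and 3 lower (2 and 3 over the list alone), with a median of 0.07, a mean of -0.10 and a test that pointed down (adjusted p = 0.814). The peptide gene nlp-29, which infection and wounding induce, was at 12.84 in wild type and 13.09 in the kin-1-labelled animals (0.26 ± 0.10, adjusted p = 0.103). It was called in 6 other settings: without crh-1 replicate 1 (0.0416), with the mean of log2 probe values (0.0338), with either table of the authors' values (0.0382), with an offset of 50 (0.0471) and with trend and robust eBayes (0.0142). The peptide gene nlp-31 differed by 0.10 ± 0.07 (adjusted p = 0.376). Of 11 caenacins, 2 were higher and 1 lower (3 and 1 over the list alone; median 0.17, adjusted p = 0.308). The caenacin gene cnc-2 differed by -0.31 ± 0.15 (adjusted p = 0.173). The call for cnc-4, at 9.64 and 9.16 (-0.48 ± 0.14, adjusted p = 0.0338), was lost without wild-type replicate 1 (0.107), wild-type replicate 2 (0.0983) or any of the kin-1 replicates (0.0617, 0.080 and 0.0963). Of 36 fungus-induced protein genes, 11 were higher and 1 lower (11 and 1 over the list alone; median 0.17, adjusted p = 0.000482), but adjusted p = 0.064 with an estimated correlation. There fipr-23 rose by 1.83 ± 0.09 (adjusted p = 1.47e-05) and fipr-22 by 1.40 ± 0.14 (0.000457), and fipr-24 was at least 1.23-fold higher (5.00 and 6.94, adjusted p = 0.00072). These 3 genes lie within 200 places of kin-1 in the gene order, near tdpt-1, where a strain difference linked to kin-1 stayed open. In a test chosen after the results were seen, the other 33 members had 8 higher and 1 lower (median 0.15, adjusted p = 0.00891, and 0.138 with an estimated correlation). Of 38 other antimicrobial effectors, 11 were higher and 3 lower (14 and 3 over the list alone; median 0.24, adjusted p = 0.00279).

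Glutathione S-transferases and cytochrome P450 genes were also higher in the kin-1-labelled animals, while UDP-glucuronosyltransferases did not pass. Of 44 glutathione S-transferases, 11 were higher and 1 lower (13 and 1 over the list alone; median 0.25, adjusted p = 0.000184). The gene gst-20 rose by 1.36 ± 0.07 (adjusted p = 1.77e-05), gst-15 by 1.31 ± 0.13 (0.000399) and gst-30 by 2.28 ± 0.13 (2.63e-05), from a wild-type mean of 6.54 that lay under the floor with 1 of 3 arrays under it. Of 75 cytochrome P450 genes, 23 were higher and 4 lower (27 and 5 over the list alone; median 0.18, adjusted p = 0.000637). Of 15 oxidative and metal stress genes, 4 were higher and 0 lower (4 and 0 over the list alone; median 0.12, adjusted p = 0.0302), but adjusted p = 0.166 with an estimated correlation. Of 61 ribosomal protein genes, 8 were higher and 0 lower, and 0 and 0 over the list alone (median 0.14, adjusted p = 4.38e-05). The gene rpl-14 rose by 0.43 ± 0.10 (adjusted p = 0.0156), lost without kin-1 replicate 1 (0.0548) or 3 (0.0533). Of 13 pharynx genes, 5 were higher and 1 lower (6 and 1 over the list alone; median 0.27, adjusted p = 0.0115), but adjusted p = 0.064 with an estimated correlation.

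The remaining lists did not pass the test between kin-1-labelled and wild-type animals. Insulin-like peptides had 11 of 40 members higher and 3 lower (median 0.26, adjusted p = 0.0519), histones 7 of 56 and 0 (0.07, adjusted p = 0.0534), vitellogenins 0 of 6 and 3 (-0.19, adjusted p = 0.0534) and osmotic stress genes 0 of 11 and 3 (-0.16, adjusted p = 0.0698). The 32 insulin-like members not near kin-1 had 6 higher and 3 lower (median 0.17, camera adjusted p = 0.336), in a test chosen after the results were seen. Intestinal genes had 2 of 13 higher and 0 lower (0.08, adjusted p = 0.104), major sperm proteins 0 of 30 and 0, cAMP and CREB signalling genes 4 of 20 and 2 (0.08, adjusted p = 0.218) and body wall muscle genes 2 of 13 and 1 (0.08, adjusted p = 0.223). Lipid metabolism genes had 2 of 25 higher and 7 lower (-0.01, adjusted p = 0.358), UDP-glucuronosyltransferases 11 of 67 and 7 (0.01, and -0.01 after cyclic loess; adjusted p = 0.434), epidermal genes 3 of 11 and 5 (-0.21, adjusted p = 0.749) and lysozymes 3 of 16 and 3 (-0.10, adjusted p = 0.881). C-type lectins had 30 of 258 higher and 40 lower, with a median of -0.02 and a mean of 0.02 (adjusted p = 0.906). Heat shock and unfolded protein genes had 1 of 13 higher and 1 lower, with a median of 0.04 and a mean of 0.08 where the test pointed down (adjusted p = 0.988). Embryonic zygotic genes had 0 of 15 higher and 0 lower, with a median of -0.02 where the test pointed up (adjusted p = 0.929), and reference genes 1 of 11 and 0 (-0.02, adjusted p = 0.985).

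The mean of the kin-1 gene itself was 13.06 in wild type and 12.82 in the kin-1-labelled animals (-0.25 ± 0.07, adjusted p = 0.040), a call lost without any of the wild-type replicates (adjusted p = 0.121, 0.0784 and 0.0884), any of the kin-1 replicates (0.064, 0.0932 and 0.112) or crh-1 replicates 1 (0.0521) or 3 (0.0509). The call was also lost with the mean of log2 probe values (-0.08, adjusted p = 0.417) and with the 2 strains fitted alone (0.0508). Over 42 probes of 7 kin-1 targets the differences ran from -0.52 to 1.13 with a median of 0.03. In target a, which gave the gene value, probes at positions 173 and 702 rose by 0.70 and 0.35. Those at positions 359, 467, 945 and 997 differed by -0.36, -0.36, -0.31 and -0.52. The value of -0.25 thus stands for probes that went both ways. All probes of target c rose, by 0.74 to 1.13. Each tested among all targets, a and b differed by -0.25 (adjusted p = 0.0386) and -0.23 (0.0344), but c by 0.85 (0.000309). The kin-1 targets e, h, j and l differed by 0.07, 0.10, 0.09 and 0.02 and were not called. The crh-1 gene was at 12.89 and 12.95 in the same animals (0.07 ± 0.12, adjusted p = 0.73). The position of the ok338 change relative to these probes was not given in the sources used here, so the probes could not check the label.

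**Figure D1:**
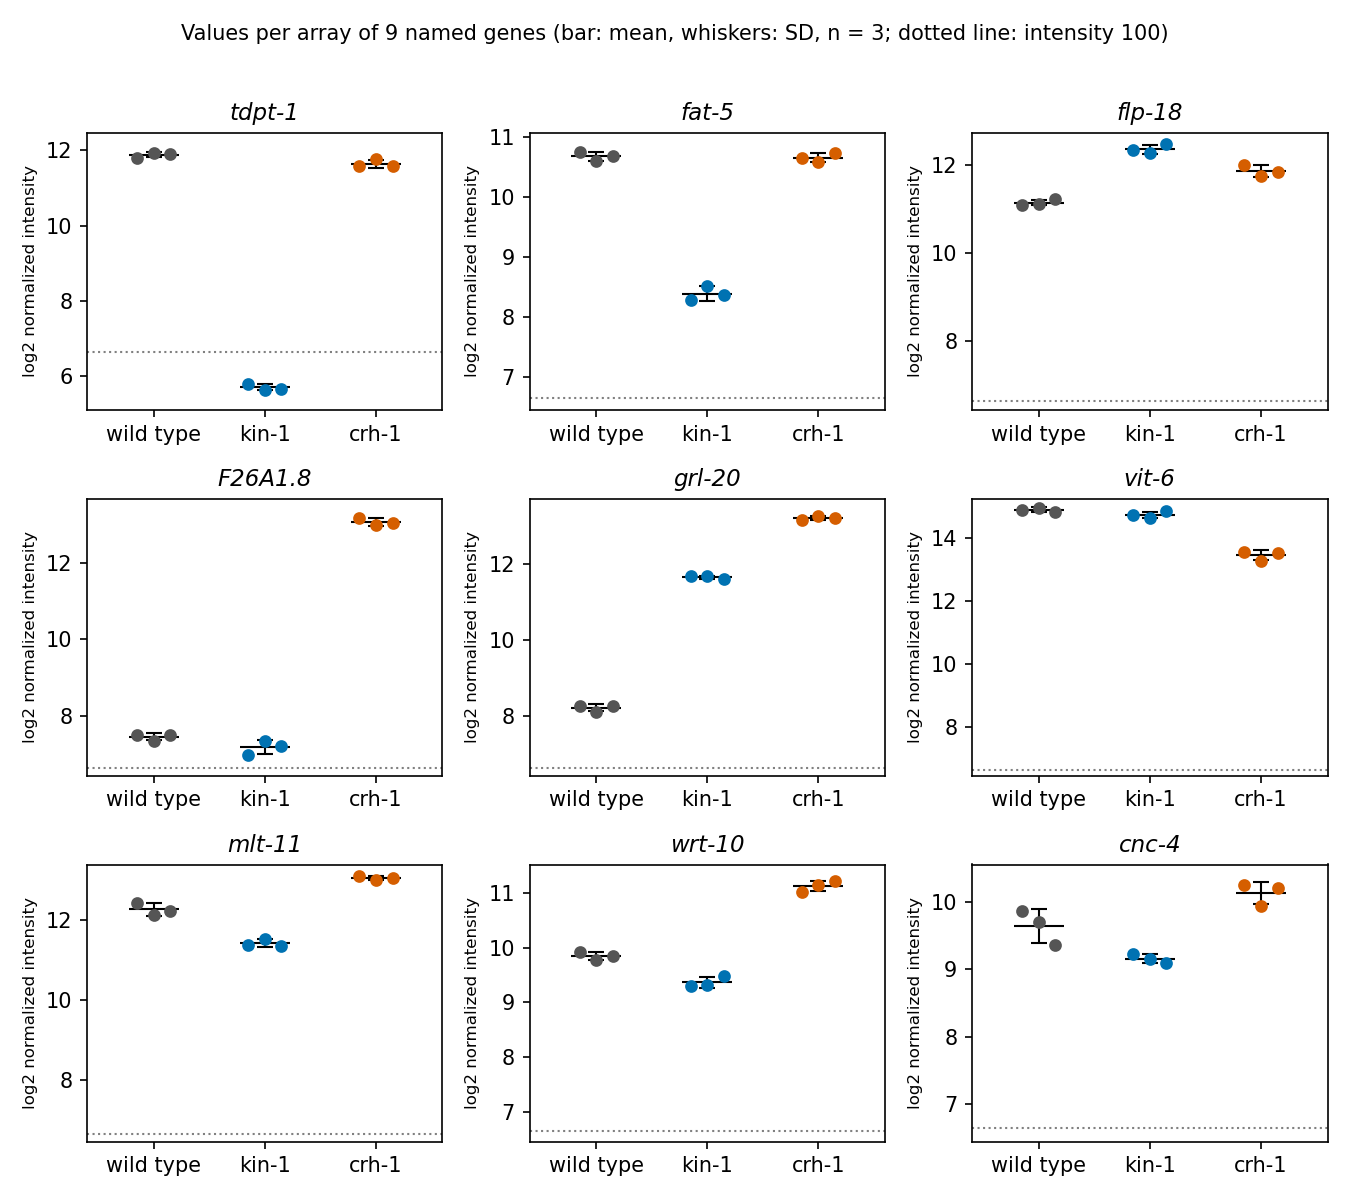
Log2 normalized intensity (vertical axis) of 9 named genes in wild-type, kin-1-labelled and crh-1-labelled animals (horizontal axis), where each point was 1 array, bars were means and whiskers SD of 3 arrays. Means of tdpt-1 were 11.88, 5.72 and 11.64, and the dotted line marked an intensity of 100.

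Against wild type, the crh-1-labelled animals had less transcript of oocyte, egg shell, yolk, sperm and germline genes. They had more of genes that build and shed the cuticle, of epidermal genes and of neuropeptides. Their epidermal antimicrobial peptide genes nlp-29, nlp-31 and cnc-2 were higher than in wild type. Of the 20018 genes, 3589 were higher and 4004 were lower, and 330 and 428 of them by a fitted difference of at least 2-fold, or 239 and 300 by measured levels or a bound. The median called difference was 0.53. The share of called genes that were higher was 47.3%, and it was 50.2% after cyclic loess between arrays, so which direction held more genes depended on the scaling. In 555 of the 7593 called genes both strains lay under the floor.

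The largest rise with both strains above the floor was that of F26A1.8, from 7.46 (SD 0.09) in wild type to 13.06 (SD 0.09) in the crh-1-labelled animals (5.60 ± 0.11, adjusted p = 3.00e-08). The ground-like gene grl-20 rose from 8.23 to 13.20 (4.97 ± 0.07, adjusted p = 6.98e-09), the cuticlin gene cut-1 from 7.74 to 12.61 (4.86 ± 0.12, adjusted p = 9.64e-08) and the collagen gene col-36 from 7.97 to 12.58 (4.62 ± 0.10, adjusted p = 4.43e-08). The collagen genes col-37 and col-158 were at least 14-fold (5.74 and 10.45, adjusted p = 5.59e-07) and at least 11.1-fold higher (5.43 and 10.12, adjusted p = 3.97e-07). The largest falls by fitted difference ended under the floor, where their sizes were only bounded. C15A11.7 was at least 5.07-fold lower (8.98 and 5.48, adjusted p = 1.99e-06), T05E12.3 at least 4.67-fold (8.87 and 5.08, adjusted p = 3.50e-05), srw-85 at least 4.14-fold (8.69 and 4.77, adjusted p = 4.02e-06) and sqst-3 at least 3.55-fold (8.47 and 5.24, adjusted p = 6.77e-06). F19C7.6 was at least 3.38-fold lower (8.40 and 4.79, adjusted p = 5.59e-07) and F19C7.5 at least 2.39-fold (7.90 and 4.68, adjusted p = 3.80e-06).

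Genes of eggs, yolk, sperm and germline fell broadly in the crh-1-labelled animals. Of 25 oocyte and egg shell genes, 0 were higher and 25 lower (0 and 25 over the list alone; median -0.86, adjusted p = 6.3e-15). The egg permeability barrier gene perm-2 fell from 13.56 to 12.14 (-1.42 ± 0.07, adjusted p = 3.47e-06), nos-2 from 11.44 to 10.06 (-1.38 ± 0.08, adjusted p = 6.10e-06) and oma-2, which acts in oocyte maturation, from 13.71 to 12.68 (-1.03 ± 0.07, adjusted p = 1.94e-05). Of 6 vitellogenins, which encode yolk proteins, 0 were higher and 6 lower (0 and 6 over the list alone; median -0.82, adjusted p = 2.19e-05). There vit-1 fell from 12.00 to 10.48 (-1.52 ± 0.08, adjusted p = 5.47e-06), vit-6 from 14.89 to 13.45 (-1.44 ± 0.10, adjusted p = 1.73e-05) and vit-5 by 0.88 ± 0.09 (adjusted p = 0.000111). Of 50 sperm genes, 0 were higher and 41 lower (0 and 42 over the list alone; median -0.59, adjusted p = 2.01e-14), with ssp-37 at -1.63 ± 0.22 (adjusted p = 0.000536) and ssp-36 down from 8.59 to 7.59 (adjusted p = 0.000124), while spe-36 was called with both strains under the floor (adjusted p = 0.00246).

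Of 30 major sperm proteins, 0 were higher and 24 lower in the crh-1-labelled animals (0 and 27 over the list alone; median -0.40, adjusted p = 1.04e-08), but adjusted p = 0.05001 with an estimated correlation, which was just over the threshold. Among them msp-77 differed by -0.51 ± 0.08 (adjusted p = 0.0011), msp-79 by -0.50 ± 0.07 (0.000587) and msp-55 by -0.49 ± 0.08 (0.0012). Of 24 genes of germline proliferation and meiosis, 0 were higher and 21 lower (0 and 22 over the list alone; median -0.50, adjusted p = 1.15e-08). The germline RNA-binding gene gld-1 differed by -0.81 ± 0.12 (adjusted p = 0.000873), the cyclin gene cyb-1 by -0.71 ± 0.09 (0.000516) and the P granule gene pgl-1 by -0.68 ± 0.09 (0.00068).

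Cuticle and epidermal genes rose in the crh-1-labelled animals. Of 18 moulting genes, 14 were higher and 0 lower (14 and 0 over the list alone; median 0.79, adjusted p = 6.9e-08). There nhr-25 went up from 8.47 to 10.15 (1.68 ± 0.11, adjusted p = 1.31e-05), the fibrillin gene fbn-1 from 7.98 to 9.15 (1.17 ± 0.14, adjusted p = 0.000318) and noah-1, which encodes an apical matrix protein, from 10.63 to 11.75 (1.12 ± 0.06, adjusted p = 6.41e-06). Of 11 epidermal genes, 9 were higher and 0 lower (9 and 0 over the list alone; median 0.84, adjusted p = 2.32e-05). The hedgehog-related genes wrt-10 and grd-10 rose by 1.28 ± 0.09 (adjusted p = 1.76e-05) and 1.17 ± 0.09 (4.32e-05). Of 176 cuticle collagens, 70 were higher and 37 lower (74 and 40 over the list alone; median 0.16, adjusted p = 0.00471).

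Neuropeptide and neuronal genes also rose in the crh-1-labelled animals. Of 31 FMRFamide-like peptide genes, 23 were higher and 0 lower (25 and 1 over the list alone; median 0.52, adjusted p = 1.09e-08). Among them flp-17 rose by 1.02 ± 0.10 (adjusted p = 0.000122), flp-8 by 0.97 ± 0.09 (7.50e-05) and flp-26 by 0.86 ± 0.11 (0.000389). Of 19 neuronal genes, 14 were higher and 0 lower (15 and 0 over the list alone; median 0.42, adjusted p = 2.32e-05). The tyrosine hydroxylase gene cat-2 rose by 0.67 ± 0.13 (adjusted p = 0.00401), snt-1 by 0.64 ± 0.13 (0.00521, but 0.0605 with a t-test after Benjamini-Hochberg) and the glutamate decarboxylase gene unc-25 by 0.61 ± 0.08 (0.000551).

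Defence genes of the epidermis rose in part in the crh-1-labelled animals. The peptide gene nlp-29 rose from 12.84 to 13.36 (0.52 ± 0.10, adjusted p = 0.00356), nlp-31 from 12.42 to 12.85 (0.43 ± 0.07, adjusted p = 0.00142) and cnc-2 from 8.69 to 9.34 (0.65 ± 0.15, adjusted p = 0.00799). The call for cnc-4, at 9.64 and 10.13 (0.49 ± 0.14, adjusted p = 0.0203), was lost without wild-type replicate 3 (0.0522), crh-1 replicate 1 (0.0666) or crh-1 replicate 3 (0.0635). As a list the antimicrobial nlp peptides did not pass, with 5 of 10 higher and 1 lower (5 and 1 over the list alone; median 0.29, adjusted p = 0.069). Of 11 caenacins, 6 were higher and 1 lower (7 and 1 over the list alone; median 0.49, adjusted p = 0.0219), but adjusted p = 0.195 with an estimated correlation. Of 23 epidermal immune signalling genes, 10 were higher and 0 lower (10 and 0 over the list alone; median 0.26, adjusted p = 0.000773). Fungus-induced proteins had 12 of 36 members higher and 3 lower, with a median of -0.01, a mean of 0.14 and a test that pointed up (adjusted p = 0.189).

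Among other lists, 29 of 56 histones were higher and 4 lower in the crh-1-labelled animals (29 and 4 over the list alone; median 0.23, adjusted p = 0.000253), but adjusted p = 0.279 with an estimated correlation. The linker histone genes hil-7, hil-3 and his-24 rose by 1.03 ± 0.13 (adjusted p = 0.000431), 0.69 ± 0.12 (0.00188) and 0.67 ± 0.12 (0.00262). Of 13 pharynx genes, 6 were higher and 0 lower (6 and 0 over the list alone; median 0.27, adjusted p = 0.000865). Of 61 ribosomal protein genes, 8 were higher and 1 lower (4 and 1 over the list alone; median 0.16, adjusted p = 0.00109).

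The remaining lists did not pass between crh-1-labelled and wild-type animals. The cAMP and CREB signalling genes had 9 of 20 members higher and 2 lower (median 0.22, adjusted p = 0.0534), osmotic stress genes 5 of 11 and 0 (0.23, adjusted p = 0.0534), UDP-glucuronosyltransferases 19 of 67 and 10 (0.12, adjusted p = 0.105) and cytochrome P450 genes 17 of 75 and 8 (0.08, adjusted p = 0.141). Embryonic zygotic genes had 2 of 15 higher and 0 lower (0.20, adjusted p = 0.251), lysozymes 1 of 16 and 2 (-0.13, adjusted p = 0.460), heat shock genes 4 of 13 and 1 (0.15, adjusted p = 0.466) and lipid metabolism genes 3 of 25 and 3 (0.02, adjusted p = 0.735). Insulin-like peptides had 12 of 40 higher and 7 lower, with a median of 0.09 and a mean of -0.01 (adjusted p = 0.413). C-type lectins had 44 of 258 higher and 52 lower (-0.02, adjusted p = 0.814), other antimicrobial effectors 6 of 38 and 6 (-0.01, adjusted p = 0.929) and body wall muscle genes 0 of 13 and 0 (0.02, adjusted p = 0.962). Oxidative and metal stress genes had 1 of 15 higher and 3 lower (-0.02, and 0.00 after cyclic loess; adjusted p = 0.670), and reference genes 1 of 11 and 0 (-0.04, and 0.01 after cyclic loess; adjusted p = 0.881). Glutathione S-transferases had 7 of 44 higher and 7 lower, with a median of 0.02 and a mean of -0.05 (adjusted p = 0.929). Intestinal genes had 1 of 13 higher and 2 lower, with a median of 0.01, a mean of -0.02 and a test that pointed down (adjusted p = 0.929).

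The crh-1 gene was at 12.89 in wild type and 12.66 in the crh-1-labelled animals (-0.23 ± 0.12, adjusted p = 0.158). It passed in 4 other settings: with the mean of log2 probe values (0.0193), with either table of the authors' values (0.0206) and with trend and robust eBayes (0.0302). Its targets a, b and c, each tested among all targets, differed by -0.28 (adjusted p = 0.0101), -0.38 (0.00356) and -0.35 (0.00592). Over 25 probes of 5 targets the differences ran from -0.79 to 0.14 with a median of -0.30. The probe with the highest position in targets a to e differed by -0.74, -0.56, -0.75, -0.79 and -0.65. In the kin-1-labelled animals the same probes differed by 0.18, -0.08, 0.10, 0.22 and 0.28. Probes in the middle of a, b, d and e differed by -0.03, -0.29, -0.04 and 0.14 in the crh-1-labelled animals, but those at position 1 of a and b by -0.35 and -0.76. The kin-1 gene differed by 0.07 ± 0.07 (adjusted p = 0.495). The position of the tz2 change relative to the crh-1 probes was not given in the sources used here. The falls at single crh-1 probes could therefore not be tied to the label.

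Compared with the kin-1-labelled animals, the crh-1-labelled animals had more transcript of moulting, collagen and epidermal genes. They had less of oocyte, yolk, sperm and germline genes and of glutathione S-transferases. Of the 20018 genes, 2485 were higher and 3194 lower, and 539 and 368 of them by a fitted difference of at least 2-fold, or 442 and 267 by measured levels or a bound. The median called difference was 0.52. In 450 of the 5679 called genes both strains lay under the floor. The median over all genes was -0.04, and the share of called genes that were higher was 43.8%, and 49.7% after cyclic loess between arrays.

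The largest rise by fitted difference in this direct comparison was that of tdpt-1, at least 31.8-fold higher in the crh-1-labelled animals (means 5.72 and 11.64, adjusted p = 5.47e-09). F26A1.8 rose from 7.19 to 13.06 (5.86 ± 0.11, adjusted p = 2.00e-08) and C14C6.3 from 6.55, a mean under the floor with 2 of 3 arrays under it, to 10.07 (3.52 ± 0.10, adjusted p = 2.97e-07). The genes gtnt-8, gtnt-56 and gtnt-57 were at least 6.64-fold (5.79 and 9.38, adjusted p = 5.55e-07), 4.37-fold (5.10 and 8.77, adjusted p = 2.27e-05) and 3.61-fold higher (4.94 and 8.50, adjusted p = 1.05e-06). The calcium-binding protein gene cex-1 fell from 11.98 to 8.64 (-3.34 ± 0.13, adjusted p = 7.74e-07). D1086.9 was at least 9.22-fold lower (9.85 and 5.87, adjusted p = 7.15e-08), C15A11.7 at least 5.96-fold (9.22 and 5.48, adjusted p = 1.25e-06) and C54F6.15 at least 4.79-fold (8.90 and 4.93, adjusted p = 2.05e-05). The genes irld-53 and F19C7.6 were at least 3.22-fold (8.33 and 4.25, adjusted p = 7.17e-06) and at least 3.12-fold lower (8.29 and 4.79, adjusted p = 6.73e-07).

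Moulting, collagen and epidermal genes differed between the mutants. Of 18 moulting genes, 17 were higher and 0 lower in the crh-1-labelled than in the kin-1-labelled animals (17 and 0 over the list alone; median 1.11, adjusted p = 4.61e-15). The gene fbn-1 rose by 1.83 ± 0.14 (adjusted p = 2.80e-05), noah-1 by 1.64 ± 0.06 (7.89e-07) and mlt-11 by 1.64 ± 0.09 (6.41e-06). Of 176 cuticle collagens, 89 were higher and 26 lower (99 and 28 over the list alone; median 0.41, adjusted p = 3.64e-10). The collagen gene col-74 was at least 2.73-fold higher (4.98 and 8.09, adjusted p = 1.14e-05) and dpy-14 at least 2.45-fold (4.96 and 7.94, adjusted p = 1.34e-06), while col-8 fell from 13.97 to 11.27 (-2.69 ± 0.09, adjusted p = 5.55e-07). Of 11 epidermal genes, 8 were higher and 0 lower (8 and 0 over the list alone; median 0.78, adjusted p = 4.34e-06), with wrt-10 up by 1.76 ± 0.09 (adjusted p = 2.85e-06), the collagen gene dpy-7 by 1.47 ± 0.11 (2.05e-05) and wrt-2 by 1.29 ± 0.09 (1.35e-05).

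Reproductive genes were lower in the crh-1-labelled than in the kin-1-labelled animals. Of 25 oocyte and egg shell genes, 0 were higher and 20 lower (0 and 23 over the list alone; median -0.50, adjusted p = 3.69e-10). There perm-2 differed by -1.23 ± 0.07 (adjusted p = 6.50e-06), nos-2 by -1.12 ± 0.08 (1.57e-05) and pos-1 by -0.71 ± 0.10 (0.00081). Of 6 vitellogenins, 0 were higher and 6 lower (0 and 6 over the list alone; median -0.61, adjusted p = 4.38e-05). Among them vit-6 differed by -1.28 ± 0.10 (adjusted p = 2.70e-05), vit-1 by -1.23 ± 0.08 (1.36e-05) and vit-4 by -0.68 ± 0.08 (0.00028). Of 24 genes of germline proliferation and meiosis, 0 were higher and 11 lower (0 and 20 over the list alone; median -0.28, adjusted p = 4.02e-05), with htp-3 at -0.45 ± 0.08 (adjusted p = 0.00327), syp-3 at -0.44 ± 0.07 (0.0020) and cyb-3 at -0.42 ± 0.07 (0.00199). Of 50 sperm genes, 1 was higher and 21 lower (1 and 21 over the list alone; median -0.24, adjusted p = 0.000727), with ssp-37 at -1.28 ± 0.22 (adjusted p = 0.00269, but 0.0655 with a t-test after Benjamini-Hochberg) and ssp-31 at -0.69 ± 0.08 (0.000272). Of 30 major sperm proteins, 0 were higher and 21 lower (0 and 24 over the list alone; median -0.31, adjusted p = 1.98e-07), but adjusted p = 0.064 with an estimated correlation.

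Defence and stress genes differed between the mutants in mixed directions. Antimicrobial nlp peptides had 6 of 10 members higher and 2 lower in the crh-1-labelled animals (7 and 2 over the list alone; median 0.34, adjusted p = 0.0111), but adjusted p = 0.064 with an estimated correlation. Of 11 caenacins, 6 were higher and 2 lower (6 and 2 over the list alone; median 0.42, adjusted p = 0.0396), but adjusted p = 0.235 with an estimated correlation. The caenacin genes cnc-2 and cnc-4 rose by 0.96 ± 0.15 (adjusted p = 0.0015) and 0.97 ± 0.14 (0.000867), and nlp-31 by 0.34 ± 0.07 (0.00693). The gene nlp-29 differed by 0.26 ± 0.10 (adjusted p = 0.0832). That call was made in 8 other settings: without crh-1 replicate 1 (0.0152), with the mean of log2 probe values (0.0106), with either table of the authors' values (0.0324), with an offset of 50 (0.0368), without the dimmest 25% of genes (0.047), with trend and robust eBayes (0.010) and without the genes under 100 on every array (0.043). Of 38 other antimicrobial effectors, 3 were higher and 17 lower (4 and 17 over the list alone; median -0.23, adjusted p = 0.00978), and of 44 glutathione S-transferases 3 were higher and 13 lower (3 and 13 over the list alone; median -0.18, adjusted p = 0.00767). Of 11 osmotic stress genes, 4 were higher and 0 lower (4 and 0 over the list alone; median 0.26, adjusted p = 0.0021), but adjusted p = 0.0518 with an estimated correlation. The inositol transporter gene hmit-1.1 rose by 1.41 ± 0.12 (adjusted p = 4.53e-05), osr-1 by 1.28 ± 0.08 (8.29e-06) and osm-8 by 1.19 ± 0.09 (1.95e-05).

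Of 15 oxidative and metal stress genes, 2 were higher and 4 lower in the crh-1-labelled than in the kin-1-labelled animals (2 and 5 over the list alone; median -0.21, adjusted p = 0.0376), but adjusted p = 0.176 with an estimated correlation. Of 56 histones, 9 were higher and 4 lower (8 and 3 over the list alone; median 0.14, adjusted p = 0.00471), but adjusted p = 0.387 with an estimated correlation. The linker histone gene hil-1 fell from 11.57 to 9.81 (-1.76 ± 0.12, adjusted p = 1.40e-05), while hil-7 rose by 0.74 ± 0.13 (adjusted p = 0.00334, but 0.0609 with a t-test after Benjamini-Hochberg). The kin-1 gene was higher by 0.32 ± 0.07 (adjusted p = 0.0114), a call lost with the mean of log2 probe values (0.19, adjusted p = 0.0675). The crh-1 gene differed by -0.30 ± 0.12 (adjusted p = 0.0903). It was called in 7 other settings, among them without crh-1 replicate 3 (0.038), with the mean of log2 probe values (0.0161), with either table of the authors' values (0.0135) and with trend and robust eBayes (0.0069).

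The remaining lists did not pass between the mutants. Fungus-induced proteins had 6 of 36 members higher and 16 lower in the crh-1-labelled animals (median -0.30, adjusted p = 0.0978), neuronal genes 1 of 19 and 0 (0.17, adjusted p = 0.141), lipid metabolism genes 7 of 25 and 2 (0.04, adjusted p = 0.144) and embryonic zygotic genes 0 of 15 and 0 (0.21, adjusted p = 0.147). Intestinal genes had 0 of 13 higher and 3 lower (-0.09, adjusted p = 0.155), pharynx genes 5 of 13 and 1 (0.05, adjusted p = 0.189), UDP-glucuronosyltransferases 14 of 67 and 12 (0.11, adjusted p = 0.202) and cAMP and CREB signalling genes 3 of 20 and 1 (0.02, adjusted p = 0.30). Cytochrome P450 genes had 10 of 75 higher and 18 lower (-0.14, adjusted p = 0.328), body wall muscle genes 1 of 13 and 3 (-0.03, adjusted p = 0.528), FMRFamide-like peptides 2 of 31 and 6 (-0.08, adjusted p = 0.721) and insulin-like peptides 4 of 40 and 9 (-0.08, adjusted p = 0.775). Heat shock genes had 2 of 13 higher and 1 lower, with a median of 0.19 and a mean of -0.03 (adjusted p = 0.202). Lysozymes had 2 of 16 higher and 6 lower, with a median of 0.09, a mean of -0.10 and a test that pointed down (adjusted p = 0.929). Ribosomal protein genes had 0 of 61 higher and 0 lower, with a median of 0.00 and a mean of -0.01 (adjusted p = 0.881), C-type lectins 39 of 258 and 42 with 0.00 and -0.06 (adjusted p = 0.962) and epidermal immune signalling genes 1 of 23 and 3 with 0.00 and -0.02 (adjusted p = 0.930). Reference genes had 1 of 11 higher and 1 lower (-0.02, and 0.03 after cyclic loess; adjusted p = 0.985).

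**Figure D2:**
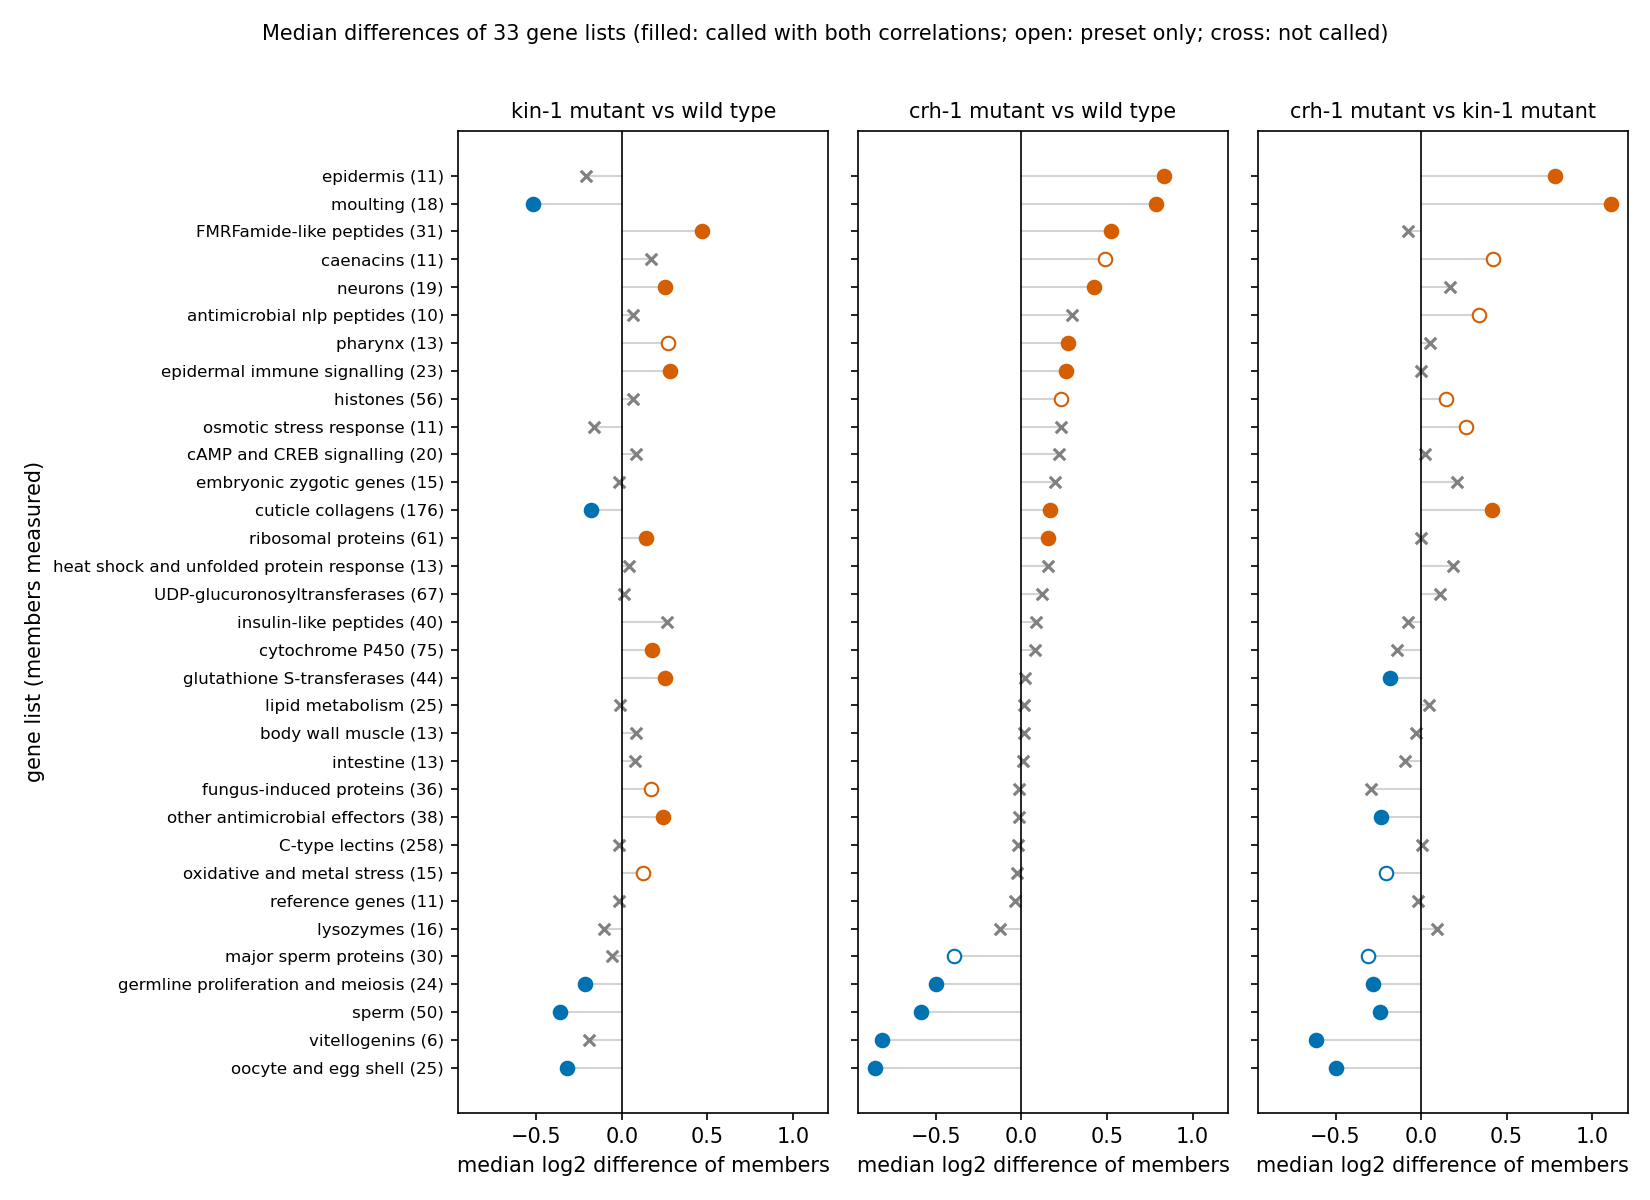
Median log2 difference of the members of each of 33 fixed gene lists (horizontal axis) in the 3 comparisons, with the number of members beside each name (vertical axis). Filled points passed camera with both correlations, open points only with the preset correlation, and crosses did not pass; moulting genes had medians of -0.52, 0.79 and 1.11.

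Many genes moved the same way in both mutants relative to the same wild-type arrays. Of the 20018 genes, 1164 were higher in both and 1438 lower in both, where independent lists of the same sizes would share 389 and 468. Simulations of all arrays without any change shared 0 and 0.01 on average. Hardly any gene is called when nothing changes, so those low counts were bound to arise. They do not measure how much of the overlap comes from the shared wild-type arrays. Across genes, which are not independent replicates, the differences of the mutants correlated with r = 0.434, and with 0.501 in the simulation of unchanged groups. The covariance was 0.0767 against 0.0146 in the simulation, an excess of 0.0621. With 3 wild-type arrays the controls could not be split, so part of the overlap may come from sharing them. Without wild-type replicate 2, 762 genes were higher in both and 938 lower in both, and without wild-type replicate 1, 850 were lower in both. Genes called in opposite directions numbered 495, of which 403 were lower in the kin-1-labelled and higher in the crh-1-labelled animals and 92 the reverse. The numbers that independent lists would give were not computed for opposite directions. These counts are therefore not shown to exceed what unrelated lists of such sizes would share.

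Ranked by the mean of the fitted differences, the genes with the largest shared rises were grl-20 (3.41 and 4.97 in the kin-1-labelled and crh-1-labelled animals), cut-1 (3.06 and 4.86, with means of 7.74, 10.81 and 12.61) and col-37 (at least 5.43-fold and at least 14-fold, with means of 5.74, 9.09 and 10.45). By the same ranking, the largest shared falls were those of srw-85 (at least 4.14-fold in both, with means of 8.69, 5.30 and 4.77), ins-8 (at least 1.98-fold in both, with means of 7.63, 5.08 and 4.43) and T05E12.3 (-1.75 in the kin-1-labelled animals and at least 4.67-fold in the crh-1-labelled animals, with means of 8.87, 7.12 and 5.08). Genes lower in both had medians of -0.43 and -0.65, and 539 of them were lower still in the crh-1-labelled animals by the direct test, against 28 in the kin-1-labelled animals. Genes higher in both had medians of 0.49 and 0.52, with 189 further up in the crh-1-labelled and 136 further up in the kin-1-labelled animals.

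**Figure D3:**
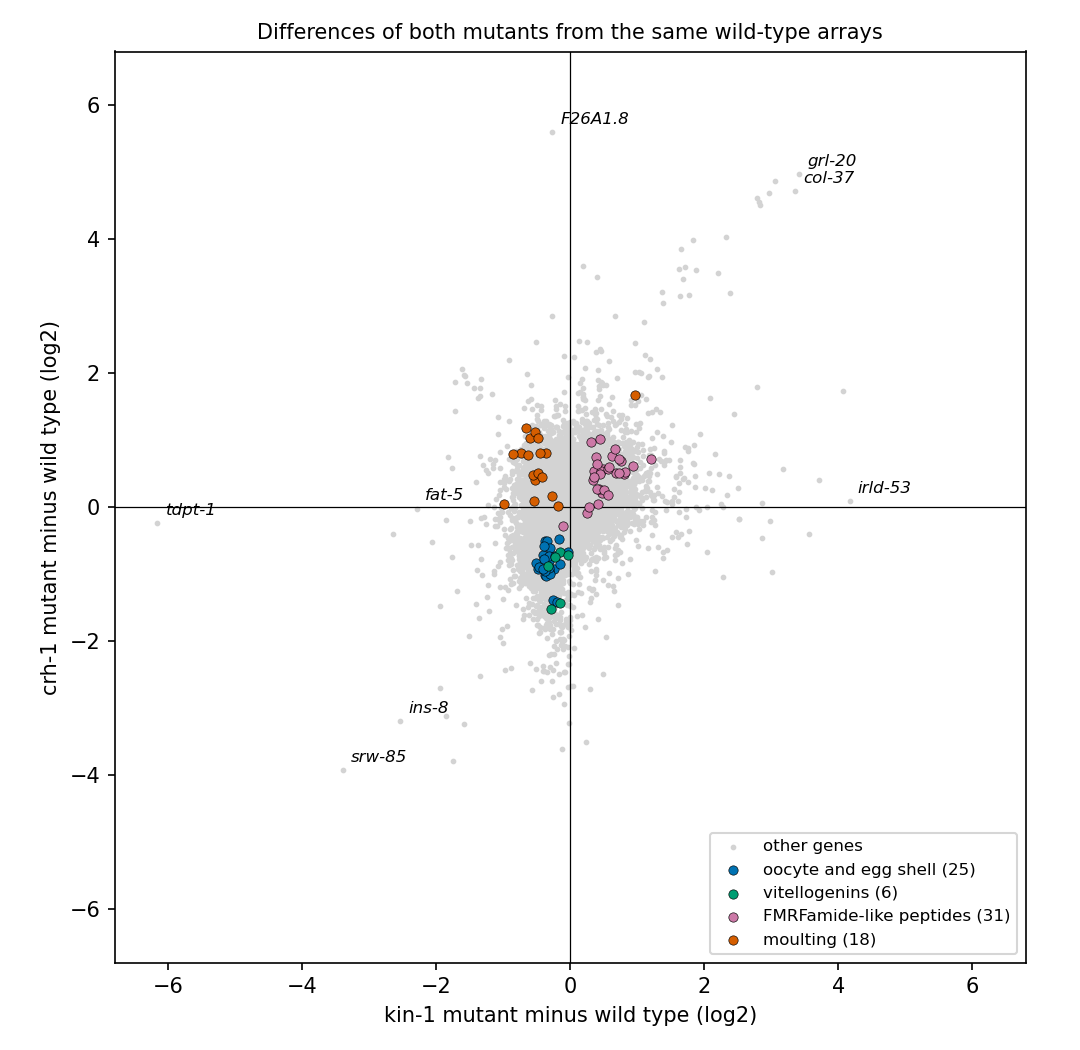
Log2 difference from wild type in the kin-1-labelled (horizontal axis) and crh-1-labelled animals (vertical axis), where each point was 1 of 20018 genes and colours marked oocyte and egg shell genes, vitellogenins, FMRFamide-like peptides and moulting genes. Moulting genes had medians of -0.52 and 0.79.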

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

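The tests on brightness and on regrouped arrays were written before the results were seen, and the tests on the moulting list, on col-19, on the probes of tdpt-1 and on the neighbours of kin-1 without tdpt-1, by measured levels and by fitted differences, were chosen after the results were seen.

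Oocyte, sperm, germline and vitellogenin genes were lower in crh-1-labelled arrays. Scaling of the arrays by brightness could make bright genes fall together. Genes matched on brightness had a median log2 difference of -0.00263, against -0.65 for the 105 genes, and the lowest median of 10000 random matched lists was -0.20. The listed genes thus fell relative to genes of like brightness. The arrays had been quantile normalized, which by itself brings matched genes close to no difference, so this could not decide on scaling. Animals less advanced in development at harvest are a candidate explanation, because moulting genes, which act before adulthood, had a median of 0.79 and because the adult collagen gene col-19 fell from 14.75 to 12.52 (log2 difference -2.23 ± 0.08, adjusted p = 5.59e-07). The arrays cannot separate a delay from an effect of crh-1 on these genes in animals of the same age. A series of harvest times with the stage of each animal scored would separate them.

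Oocyte, sperm and germline genes were also lower in kin-1-labelled arrays, with a median of -0.32 over 99 genes. Genes matched on brightness had a median of -0.0116, with -0.116 as the lowest of 10000 random lists, so the listed genes fell relative to genes of like brightness. After quantile normalization this could not decide on scaling for this strain either. A delay such as might hold for crh-1 was taken to raise moulting genes and lower col-19. The median of moulting genes was -0.52, and col-19 differed by -0.02 (adjusted p = 0.87), so that pattern was not seen. Yet grl-20, cut-1 and nhr-25, which rose in the crh-1-labelled animals, rose here too (3.41, 3.06 and 0.96). The criterion on moulting genes and col-19 was chosen after the results were seen. It covers only a delay that acts as in crh-1, and a delay of another timing was not tested. A smaller or less active germline could be counted under the microscope.

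The loss of tdpt-1 on kin-1-labelled arrays did not look like failing probes, since 6 of 6 probes lay below their lowest wild-type value on all arrays, by 2.31 to 7.85 on log2 scale. A strain difference linked to kin-1, such as a second change carried along with ok338, is a candidate explanation. With tdpt-1 left out and runs of a family counted once, 4 genes within 200 places of kin-1 in the gene order changed by at least 2-fold by measured levels or a bound, 1.82% of 220 against 0.849% elsewhere (one-sided Fisher exact p = 0.122; exact p = 0.0233 within 50 places and 0.0865 within 100). By fitted differences, which include levels under the floor, 7 genes changed, 3.18% against 1.25% (exact p = 0.0227; exact p = 0.0127 within 50 places and 0.0193 within 100). Around crh-1, 7 of 400 genes changed by measured levels, a share of 1.75% that was no higher than elsewhere (exact p = 0.894). With so few genes, and a result that turned on levels under the floor within 100 and 200 places, a linked strain difference stayed open. Sequencing the strain around tdpt-1 would test this.

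Of 10 splits of the arrays of a comparison into 3 and 3, the real split called 4511, 7593 and 5679 genes in the kin-1, crh-1 and direct comparisons, the highest count of any other split was 0, and 1 of 10 splits called as many genes in each. With 10 splits no smaller share can be reached. Every other split mixes arrays of both strains in a group, which widens the spread there. Few calls could therefore arise in those splits, whatever set the strains apart.

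The mutants went in opposite directions from wild type in 495 genes, a number not set beside that of independent lists. All 495 also differed in the direct test, which was bound to hold and adds no separate support. The direct difference of such a gene is larger than either difference from wild type, with the same standard error. The median of the moulting list differed by 1.11 between the mutants and that of cuticle collagens by 0.41. The moulting genes mlt-11, noah-1, fbn-1 and qua-1 differed by 1.64, 1.64, 1.83 and 1.54, after -0.85, -0.52, -0.65 and -0.73 in the kin-1-labelled and 0.79, 1.12, 1.17 and 0.81 in the crh-1-labelled animals against wild type. The epidermal genes wrt-10 and wrt-2 differed by 1.76 and 1.29 (-0.49 and -0.50, then 1.28 and 0.79). The collagen gene dpy-7 differed by 1.47 (-0.57, then 0.90) and dpy-14, under the floor in wild-type and kin-1-labelled animals, by a fitted 2.97, which measured levels bounded at only 2.45-fold or more. The osmotic stress genes hmit-1.1, osr-1 and osm-8 differed by 1.41, 1.28 and 1.19 (-0.99, -0.76 and -0.54, then 0.41, 0.53 and 0.64). The fitted differences of C14C6.3, gtnt-8, gtnt-56 and gtnt-57 were 3.52, 3.59, 3.67 and 3.56. All kin-1-labelled arrays of the last 3 lay under the floor, so these were only bounded, at least 6.64-, 4.37- and 3.61-fold higher, and the kin-1-labelled mean of C14C6.3 was 6.55, with 2 of 3 arrays under the floor. The genes cex-1 and gst-15 differed by -3.34 and -1.91 (2.87 and 1.31, then -0.47 and -0.60). The fitted difference of gst-30 was -3.32, but its crh-1-labelled arrays lay under the floor, so its level there was only bounded, at least 4.50-fold below the kin-1-labelled level (means 5.50 and 8.81). The fitted difference of D1086.9 was -3.98, with its crh-1-labelled arrays under the floor and a bound of at least 9.22-fold, and cnc-4 differed by 0.97 (-0.48, then 0.49).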

How the results depend on the processing

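The tests without the 5560 genes under 100 on every array (27.8%), camera after cyclic loess and camera without the genes near kin-1 were chosen only after the results were seen. Of 173 values of the counts under other settings, 145 stayed within 1.5 times the chosen setting and 28 moved further.

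The counts moved most with the threshold and the test. At an adjusted p with 2-fold, 186 genes were higher and 82 lower in kin-1-labelled than in wild-type animals, 330 and 428 in crh-1-labelled animals, and 539 and 368 between the mutants. Shared calls at 2-fold were 46 higher and 20 lower. A t-test at p 0.05 with 1.5-fold gave 770 and 531, 1373 and 1710, and 1296 and 1022, and with 2-fold 186 and 80, 326 and 426, and 537 and 367. A t-test after Benjamini-Hochberg gave 1402 and 1488 in the kin-1 comparison and 1948 lower genes between the mutants. A fold threshold added to the same test gives fewer calls by construction. With the adjustment kept, the t-test moved 2170 and 2341 to 1402 and 1488. The t-test also left the remaining strain out of the fit, so more than the test changed. With 2-fold kept, the t-test without adjustment moved 186 and 82 only to 186 and 80.

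Leaving out an array gave 1480 to 2358 lower genes in the kin-1 comparison, with 1480 without wild-type replicate 1. Shared calls were recounted only without each wild-type array, at 762 to 873 higher and 850 to 1020 lower. The highest count of lower genes, 2358 without crh-1 replicate 2, lay above the 2341 of all arrays, and why the counts moved was not tested.

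The replicate block gave 1849 higher and 1946 lower genes against 2170 and 2341 without it, 3278 and 3710 against 3589 and 4004, and 2284 and 2790 against 2485 and 3194, none moved by over 1.5 times. The numbers did not pair the arrays, as residuals of same-numbered arrays correlated across genes at -0.077 to 0.069 over 9 pairs and others at -0.069 to 0.096 over 18 pairs. With the block, the calls of kin-1 (adjusted p = 0.0632) and mcm-2 (0.0651) in the kin-1 comparison were lost and the insulin-like list passed (0.045). Without the block, camera on this list without its members near kin-1 gave an adjusted p of 0.336. That reduced list was not tested with the block.

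Camera with an estimated correlation kept 9 of 15 list calls between the mutants, and 12 of 15 in each comparison with wild type. After cyclic loess, histones passed in the kin-1 comparison (adjusted p = 0.0328), and antimicrobial nlp peptides (0.049), cAMP and CREB signalling (0.0328) and osmotic stress genes (0.0435) in the crh-1 comparison. Without the genes under 100 on every array, 2607 genes were higher and 2861 lower, 3817 and 4293, and 2727 and 3688 in the 3 comparisons.

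For 143 results of named genes, 3132 of 3216 values kept their call or stayed uncalled, 57 lost a call, 27 gained one and 0 were reversed, while 1 uncalled difference changed sign. A further 73 values were missing because the setting did not hold the gene's target. Most of these genes were named because they were called in the same arrays. That most calls were kept is therefore partly set by the choice of genes. A t-test after Benjamini-Hochberg lost cnc-4 (adjusted p = 0.123), flp-25 (0.085), gld-1 (0.0994), mcm-2 (0.051), pie-1 (0.0749), rps-20 (0.0757) and rps-27 (0.0521) in the kin-1 comparison. It lost cnc-4 (0.119), snt-1 (0.0605) and spe-36 (0.054) in the crh-1 comparison, and hil-7 (0.0609) and ssp-37 (0.0655) between the mutants. The authors' values added 5 calls: cnc-2 lower (-0.37, adjusted p = 0.0136) and nlp-29 higher (0.0382) in the kin-1 comparison, crh-1 lower in the crh-1 comparison (-0.31, adjusted p = 0.0206), and crh-1 lower (0.0135) and nlp-29 higher (0.0324) between the mutants.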

Other observations

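Genes that changed lay beside each other more often than in a shuffled order, and windows and symbol families were tests chosen only after the results were seen. Adjacent pairs of genes that changed by at least 2-fold by measured levels or a bound numbered 17 in the kin-1 comparison, 54 in the crh-1 comparison and 78 between the mutants, against means of 1.63, 14.4 and 24.5 and maxima of 8, 25 and 43 in 1000 permutations of the order (38, 91 and 109 pairs by fitted differences). Of the measured pairs 16, 50 and 69 went the same way, and 9, 29 and 34 were of a shared family or clone, where copies that hybridize to each other's probes cannot be told apart. In kin-1-labelled animals, 7 of 20 genes from C13B7.6 to srd-61 were at least 2-fold higher by measured levels or a bound (11 by fitted differences), among them F56A4.2 (10.87 to 14.06, log2 difference 3.18), C01B4.6 (1.72), C01B4.7 (1.26) and the transporter gene mct-2 (1.16), and none of these rose by 2-fold in crh-1-labelled animals. In crh-1-labelled animals 11 of 20 genes from C14C6.5 to gtnt-56 were at least 2-fold higher by the same count (13 by fitted differences), among them K06H6.1 (-1.35 in the kin-1-labelled and 1.78 in the crh-1-labelled animals), K06H6.2 (-1.34 and 1.66), gtnt-7 (-1.72 and 1.43) and the nuclear receptor gene nhr-155 (-1.54 and 1.86, with a kin-1-labelled mean of 6.50 that lay under the floor and 2 of 3 arrays under it).

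Symbol families were tested too, some of them sharing members with the fixed lists (10 of 76 nlp and 4 of 279 nhr genes), with 133 of 741 tests on 247 families passing and 17 of these passing with an estimated correlation. Neuropeptide-like nlp genes rose in both mutants, 45 of 76 higher and 4 lower in the kin-1-labelled animals (adjusted p = 0.0222 with an estimated correlation) and 41 higher and 1 lower in the crh-1-labelled animals (0.0246). Nuclear receptor nhr genes had 70 of 279 higher and 7 lower in the kin-1-labelled animals (0.0222) and 68 and 10 in the crh-1-labelled animals (0.0308). Between the mutants, cuticlin-like cutl genes had 18 of 29 higher and 0 lower in the crh-1-labelled animals (median 0.50, 0.0308) and bus genes 11 of 14 and 1 (0.0453), while ground-like grl genes had 19 of 30 and 0 (median 1.01) but 0.071 with an estimated correlation.

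The following single genes were chosen after their values were seen and stand for no group. The superoxide dismutase gene sod-3 rose from 10.47 to 11.67 in the kin-1-labelled animals (adjusted p = 0.000123) and the metallothionein gene mtl-1 by 0.66 ± 0.08 (0.00101), while mtl-1 fell by 1.26 ± 0.08 in the crh-1-labelled animals (1.17e-05). The gene sod-5 was at least 3.66-fold higher in the kin-1-labelled animals (5.65 and 8.52, adjusted p = 2.63e-05). The thaumatin genes thn-1 and thn-2 differed from wild type by -1.08 and -1.39 in the kin-1-labelled (adjusted p = 5.45e-05 and 6.07e-05) and by -0.88 and -0.93 in the crh-1-labelled animals (5.05e-05 and 0.000164). The peptide gene nlp-25 fell by 1.25 ± 0.10 in the kin-1-labelled animals (adjusted p = 9.15e-05) and rose by 0.56 ± 0.10 in the crh-1-labelled animals (0.00193), and cnc-3 rose by 1.23 ± 0.11 in the crh-1-labelled animals (9.10e-05).

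The genes around kin-1 that changed in the kin-1-labelled animals included aex-5 (12.34 to 14.38, log2 difference 2.04), ZK909.3 (1.62) and the myosin gene unc-54 (-1.14), and none of these changed by 2-fold in the crh-1-labelled animals. They also included fipr-22 (1.40), fipr-23 (1.83) and fipr-24, which were called higher in the crh-1-labelled animals too (0.83, adjusted p = 0.00209; 0.66, adjusted p = 0.000755; and for fipr-24 adjusted p = 0.00435 with both strains under the floor). A target of kin-1, ZK909.2c, was itself higher by 0.85 ± 0.08 (adjusted p = 0.000309, among all targets), and the authors' deposited table lists it as 1.84-fold higher. The probes of this target may lie outside the stretch that ok338 changes, or in a remaining transcript; the probes of all kin-1 targets ranged up to 1.13, and 4 genes within 200 places of kin-1, with tdpt-1 left out and runs of a family counted once, changed by at least 2-fold by measured levels or a bound.

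Of the called genes with fitted changes of at least 2-fold, 143 of 268 in the kin-1 comparison, 335 of 758 in the crh-1 comparison and 334 of 907 between the mutants were absent from the authors' deposited gene table, tdpt-1 among them, and that table held almost no target under 100 on any array.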
